A study of Mus musculus with 12 samples.

How the data were processed

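Resident macrophages were taken by peritoneal lavage from male mice that were either wild type or carried a disrupted Cybb gene. Cybb encodes gp91phox, the catalytic subunit of the phagocyte NADPH oxidase, and its loss causes chronic granulomatous disease. Per the labels, cells were B220- CD115+ and were sorted as an F4/80high MHCII- or an F4/80low MHCIIhigh population, with no treatment. The 12 arrays form 4 groups of 3, named here WT_high, WT_low, KO_high and KO_low. Array WT_high 2 carries an age of 12 weeks and all others 9 weeks. Age was not part of any fit, so a change seen without WT_high 2 cannot be told apart from a difference of age. The labels number the replicates but do not state that each number is a separate animal or a separate sort, so spread between replicates is spread between arrays. Per the labels, RNA was amplified before labelling with Cy5, and amplification compresses or distorts levels by an amount that is not given in the sources used here.

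Scanner files gave, per the file headers, a processed intensity for each spot of a one-colour Agilent mouse array with probe positions on mm9, made with Agilent Feature Extraction 11.5.1.1. Per the file headers this intensity was background-subtracted and detrended within the array, with low spots set to a surrogate value and no scaling between arrays. Each array held 43020 gene spots for 39429 probes. A deposited value table gave an intensity on a linear scale for 31176 of the 39429 probes. Its columns had medians between 438.754 and 438.99 and the same highest value, 520450, so that the columns had near-identical distributions by these measures. Spearman correlations of its columns with the scanner values of the same array lay between 0.9999 and 1. Of the 8253 probes it did not list, 8218 were never well above background on any array. The labels name Partek beside Feature Extraction with no version or role, so the tool that made this table and the rule that chose its probes stay unknown. The table served as an alternative only, and 0 sample columns were left unused.

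Processed intensities were averaged over the spots of a probe after spots marked as outliers had been left out, and put on the log2 scale. Each array was scaled by subtracting its 75th percentile, and a constant of 10.4245 was added. Probes well above background, by the flag in the scanner files, on at least 3 of the 12 arrays were kept, which left 24824 probes. Probes were named through their RefSeq accession (28025 probes), the current symbol (3413), a synonym (295) or, failing these, the name in the file (7696). The probe with the highest mean signal stood for each gene, which gave 19464 genes. Of 4307 genes with several passing probes, 19 in the wild type and 12 in the knockout had probes called in opposite directions between the subsets.

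A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 with the data.table package of version 1.17.8 (moderated test, two-sided, eBayes with a mean-variance trend). The 6 comparisons were knockout against wild type in each subset, the average of these, their difference (the interaction, F4/80low minus F4/80high), and F4/80low against F4/80high in each genotype. P values were adjusted by Benjamini-Hochberg over all genes of a comparison, and a gene was called at an adjusted p under 0.05. An exact test of 3 arrays against 3 cannot go below 0.1, which is why the moderated test was used. Values are log2 differences with the model's standard error, and group levels are means with the SD over 3 arrays. A fold for a gene that no array of a group showed well above background is given as a bound. For the bound, each array of that group takes the lowest signal that any probe well above background had on that array, or the gene's own value where this was higher, and the difference from the other group's mean is written "at least". Where 1 or 2 arrays of a group were well above background the number of arrays is given with the log2 difference, a fitted value that rests in part on dim signal. A level is not compared between different probes.

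Gene lists were tested with camera (correlation between genes preset to 0.01), with camera using a correlation estimated from the data, and with fry, each adjusted over the lists of a comparison with at least 5 tested members. The 21 lists were NADPH oxidase subunits, genes beside Cybb on the X chromosome, large peritoneal macrophage genes, small peritoneal macrophage genes, MHC class II presentation, type I interferon response, interferon gamma response, inflammatory cytokines and NF-kB targets, NRF2 targets, antioxidant enzymes, glycolysis, oxidative phosphorylation, efferocytosis and scavenger receptors, LXR and PPAR lipid handling, cholesterol synthesis, cell cycle, alternative activation, lysosome and autophagy, toll-like receptor signalling, immediate early genes and heat shock response. The 9 marker lists of other cells were B cells, T and NK cells, neutrophils, mast cells, eosinophils, dendritic cells, blood monocytes, mesothelial and stromal cells, and erythrocytes. Mast cells, eosinophils, mesothelial and stromal cells, and erythrocytes had under 5 tested members and no test.

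Named genes were chosen by rule. Cybb came first. Then came the 12 highest and the 12 lowest log2 differences among called genes whose groups did not overlap and whose name is a gene symbol. Where fewer than 10 genes were called, all of them and the 5 highest and 5 lowest by moderated statistic were taken. Up to 4 members of each list with the smallest p were added. A few genes that the rule names are not reported here. The comparisons, the tests, the lists, this rule and the alternatives were chosen before the data were examined, apart from the 3 alternatives, the slope test of weak signals and the tests named as later choices in the closing section.

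The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization, scaling to the array median, the deposited table, no filter and a strict filter on dim probes, the mean of a gene's probes, every probe tested, no mean-variance trend, array weights, the compared groups alone, a replicate block, slide as a random and as a fixed block, and leaving out each array. The arrays lay on 6 slides. Slide 2 held WT_low 3, KO_high 2 and KO_low 3, slide 3 held KO_high 1 and KO_high 3, slide 4 held WT_high 3 and WT_low 1, and slide 5 held WT_high 1, WT_high 2 and KO_low 1, while WT_low 2 and KO_low 2 lay alone. Slide-blocked values come from the fit with slide as a fixed term. A within-slide value is 1 array minus 1 array on the same slide, so it has no measure of spread. Both arrays are also part of the main comparison. Within slide 2 the values between knockout subsets use KO_high 2, the array with the lowest weight (0.373). Since slide 3 holds KO_high arrays alone, its term takes up KO_high 1 and KO_high 3. Every slide-blocked value that involves KO_high therefore rests on KO_high 2 as its only KO_high array. The terms of the slides that hold WT_low 2 alone and KO_low 2 alone take up those arrays in the same way. Slide-blocked values that involve WT_low or KO_low therefore rest on arrays 1 and 3 of that group. The blocked fit has 3 residual degrees of freedom, so a call can end there without a smaller difference. The procedure was tested on simulated data, drawn once per comparison. Their noise was independent for each gene and array, so they held no correlation between genes and no slide effect, and they give no error rate for data that do. Of 19383 simulated genes, 100 were shifted by log2 1 and 100 by log2 2. In the F4/80high genotype comparison 16 and 57 of these were called, in F4/80low 16 and 60, in the average 42 and 81, in the interaction 2 and 36, and between subsets 23 and 61 in the wild type and 18 and 63 in the knockout. Camera with the preset correlation gave a list of 20 unshifted genes p = 0.00338 in the interaction and 0.0346 in the average, and 0.591 to 0.936 in the other comparisons. Figures were drawn with matplotlib 3.10.9 and tables read with pandas 2.3.3 in Python 3.11.15. Control spots were left out, no reference genome was used, and cell numbers and sort purity were not analysed here.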

Results

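Gene expression was measured on one-colour arrays in 2 populations of resident peritoneal macrophages of untreated male mice. The F4/80high MHCII- cells are those usually called large peritoneal macrophages and the F4/80low MHCIIhigh cells those called small peritoneal macrophages. Each population came from wild-type mice and from mice lacking Cybb, with 3 arrays in each of the 4 groups. Between 49.8% and 51.7% of spots were well above background in WT_high, 56.2% to 58.7% in WT_low, 49.7% to 58.2% in KO_high and 56.5% to 62.4% in KO_low. The 75th percentile of signal lay between 1076 and 1848 intensity units, and 0 spots were saturated. Arrays of the same group correlated at r of 0.937 to 0.963, and the lowest r of any pair was 0.871. The number of arrays, not a count of molecules, limits the precision here.

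Cybb was well above background on all 12 arrays. Its level was 16.72 ± 0.05 (log2, mean and SD, n = 3) in WT_high, 15.92 ± 0.19 in WT_low, 15.64 ± 0.26 in KO_high and 14.04 ± 0.30 in KO_low. The single Cybb probe lies on the mm9 X chromosome at 9013216 to 9013275 on the minus strand and may lie outside the disrupted part of the gene, so that signal in the knockout is no sign of a working protein. The gates were also read as checks and not as findings. In F4/80low cells Adgre1, the gene of F4/80, was lower (log2 difference -2.24 in the wild type, adjusted p = 9.17e-05, and -2.58 in the knockout, adjusted p = 2.52e-05). H2-Aa was 3.87 and 3.61 higher, H2-Ab1 3.54 and 3.98, H2-Eb1 3.90 and 3.86, and Cd74 2.58 and 2.83. Ptprc, the gene of CD45, was 1.61 and 1.54 higher, and Csf1r, the gene of CD115, was not called in either genotype.

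**Figure D1:**
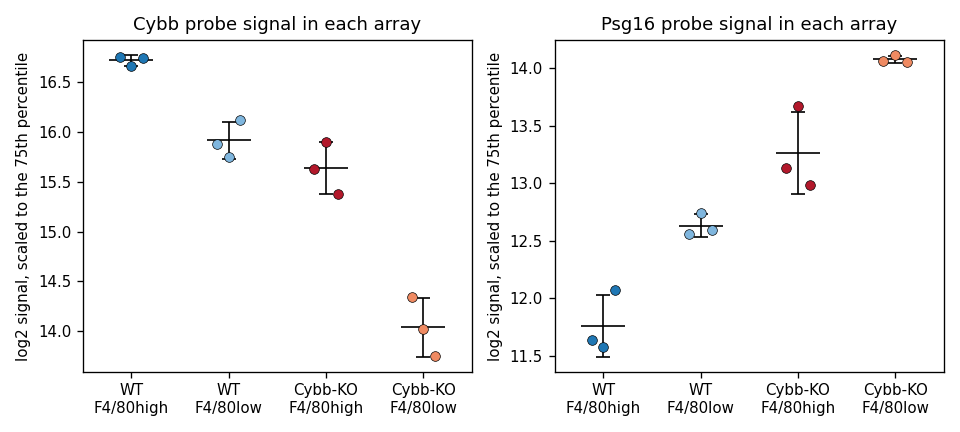
Log2 scaled intensity of Cybb and Psg16 on each array of the 4 groups, with dots for arrays, a bar at the mean of 3 arrays and a line of 1 SD. Cybb lay lower in each knockout group than in the matching wild-type group, at 15.64 against 16.72 in F4/80high and at 14.04 against 15.92 in F4/80low, while Psg16 lay higher, at 13.26 against 11.76 and at 14.08 against 12.63.

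The comparison of the subsets in wild-type mice asks how the resident populations differ. F4/80low cells had higher transcripts of the fractalkine receptor Cx3cr1 (at least 125-fold), of the integrin Itgax, which is CD11c (at least 42.0-fold), of the chemokine receptor Ccr2 (at least 49.8-fold) and of the mannose receptor Mrc1 (log2 difference 4.03 ± 0.33, SE, 16.3-fold). They had lower transcripts of the phosphatidylserine receptor Timd4 (-4.66 ± 0.28, 25.2-fold lower), of the complement receptor Vsig4 (-5.21 ± 0.33, 37.0-fold lower), of 12/15-lipoxygenase Alox15 (-4.20 ± 0.25, 18.4-fold lower) and of the fatty-acid binding protein Fabp4 (-4.91 ± 0.32, 30.0-fold lower). Higher as well were the eosinophil-associated ribonucleases Ear1 (at least 200-fold), Ear2 (at least 215-fold) and Ear12 (at least 158-fold), near-identical paralogs whose probes may read one another. Rnase2a of the same family (at least 103-fold), the ureidopropionase Upb1 (at least 83.0-fold), the adhesion receptor Cd226 (at least 64.6-fold), Trerf1 (at least 119-fold), the neurturin receptor Gfra2 (at least 64.3-fold) and the actin-severing protein Gsn (at least 52.0-fold) were higher too. Hr was 7.0 higher but well above background on only 1 of 3 WT_high arrays. Lower were the cell-cycle inhibitor locus Cdkn2a (at least 38.6-fold lower), Armc2 (at least 53.9-fold lower), Plekha6 (at least 20.5-fold lower) and the TGF-beta binding protein Ltbp1 (-6.23 ± 0.46, 75-fold lower). Tgfb2, Fscn1, Tox2 and Afap1l1 were well above background on 2 of 3 WT_low arrays, and Serpinb2, Garnl3, Cald1 and the LPS binding protein Lbp on 1, with differences of -7.31, -6.25, -6.16, -6.21, -7.30, -6.87, -6.30 and -6.21. Every gene named here was called, and its 3 WT_low arrays all lay on one side of its 3 WT_high arrays.

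Lists of genes known from the large and the small population differed between the sorted cells. Of 22 tested large peritoneal macrophage genes 20 fell and 1, Rarb, rose (1.28), with a median of -3.84. Beside Timd4 and Alox15, the transcription factor Gata6, the P-selectin gene Selp and the adhesion molecule Icam2 fell by 4.37, 4.86 and 1.5; these 3 lie outside the naming rule and were chosen after their values were seen. Of 18 small peritoneal macrophage genes 14 rose and 0 fell, with a median of 2.39, among them the Fc receptor-like gene Fcrls (5.07 ± 0.25, 33.6-fold), Ccr2, Itgax and Mrc1. MHC class II presentation had 10 of 12 genes higher and 0 lower, including the peptide-loading chain H2-DMb2 (4.38 ± 0.21, 20.8-fold), and its H2-A, H2-E and Cd74 members stand in the gate. Higher and lower counts adjusted over the list alone were 1 and 20, 16 and 0, and 11 and 0. With slide as a block the medians were -4.05, 2.12 and 2.19, and within slide 4 they were -4.18, 2.31 and 2.01. Camera called these 3 lists with the estimated correlation as well (adjusted p = 0.023, 0.0195 and 0.0195). The MHC class II list was not tested without its members in the gate.

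Markers of other cells were also higher in F4/80low. Dendritic cell genes were higher in 5 of 10 cases and lower in 0 (median 2.32, adjusted p = 0.0299 with an estimated correlation), with the transcription factor Batf3 at 3.81 ± 0.39 (14-fold), the lectin Cd209a at 2.84, the kynurenine enzyme Kmo at 2.59 and the peptidase Dpp4 at least 13.1-fold higher. B cell genes were higher in 7 of 11 cases (median 1.49, or 1.31 with bound genes at their bound; adjusted p = 0.0195 with an estimated correlation), among them Pax5 (2.05) and Cd79b (1.72), although B220+ cells were gated out. T and NK cell genes were higher in 5 of 9 cases (median 1.83, camera adjusted p = 0.000367), led by the adhesion molecule Cd2 (4.0 ± 0.43, 16-fold), but the call was lost, at adjusted p = 0.13 with an estimated correlation. Blood monocyte genes rose in 4 cases and fell in 1 of 10 (median 0.71, camera adjusted p = 0.00609, adjusted p = 0.0752 with an estimated correlation). Ccr2 and Plac8 (4.73, well above background on 2 of 3 WT_high arrays) were higher and haptoglobin, Hp, was lower (-1.92), and without WT_low 3 the camera call was lost (adjusted p = 0.0549). In these 4 lists, 8, 8, 6 and 4 genes were higher and 0, 0, 0 and 1 lower when adjusted over the list alone. Cd209a stands both in the dendritic cell and the small macrophage list, and Ccr2 both in the monocyte and the small macrophage list. Medians with slide as a block were 2.15, 1.51, 1.68 and 0.74, and within slide 4 they were 2.89, 1.54, 0.92 and 0.47.

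Uptake, redox and metabolic genes leaned the other way. Over all genes the subset difference also fell with signal. In the wild type its median was 0.54 in the lowest intensity decile and -0.32 in the brightest, and in the knockout 0.48 and -0.24. The brightest decile had 153 genes higher and 871 lower in the wild type at an unadjusted p under 0.05, and the lowest 380 and 118. No list was tested against genes of like intensity. Efferocytosis and scavenger receptor genes fell in 13 and rose in 4 of 21 cases (median -0.87), with the bridging protein Mfge8 at -3.01 ± 0.23 (8.05-fold lower), the matrix protein Thbs1 at -3.48 and Cd93 at -2.60. Timd4, Thbs1 and Cd93 are shared with the large macrophage list. Lysosome and autophagy genes fell in 10 of 21 cases and rose in 0 (median -0.57), among them the proteases Lgmn (-1.59) and Ctsd (-1.20) and the hexosaminidase Hexa (-1.12). NRF2 targets fell in 10 of 19 cases and rose in 0 (median -0.60), with thioredoxin Txn1 at -1.71, glutathione reductase Gsr at -2.61 and the transferase Gstm1 at -1.64. Antioxidant enzymes fell in 6 and rose in 1 of 15 cases (median -0.63), with the peroxidases Prdx6 (-1.42) and Gpx4 (-0.90) lower. Oxidative phosphorylation genes fell in 10 of 31 cases and rose in 0 (median -0.45), among them the complex I subunits Ndufa5 (-0.73) and Ndufa1 (-0.79), neither of which was called with normexp background correction. Camera called all 5 lists (adjusted p = 4.76e-05, 1.62e-05, 1.62e-05, 0.000447 and 5.65e-06), and each call was lost, at adjusted p = 0.0752, 0.113, 0.0752, 0.249 and 0.28 with an estimated correlation. Alternative activation genes rose in 6 and fell in 2 of 12 cases (median 1.47, camera adjusted p = 0.00218, adjusted p = 0.0752 with an estimated correlation). Mrc1, the galactose lectin Mgl2 (1.76) and the haemoglobin receptor Cd163 (1.80) were higher and the chemokine Ccl24 was lower (-1.48), and Mrc1 and Mgl2 with Clec10a and Retnla are shared with the small macrophage list. The 6 lists had higher and lower counts adjusted over the list alone of 5 and 13, 0 and 11, 0 and 12, 1 and 8, 0 and 14, and 8 and 2. Slide-blocked medians were -0.78, -0.55, -0.60, -0.39, -0.38 and 1.57, and within slide 4 they were -0.89, -0.70, -0.71, -0.34, -0.39 and 0.97. Of genes beside Cybb on the X chromosome 2 of 6 fell, Mid1ip1 (-1.03) and Tspan7, and 3 did when adjusted over the list alone (median -0.75, or -0.61 with bound genes at their bound). Their camera adjusted p was 0.0174, and the call was lost, at adjusted p = 0.0752 with an estimated correlation. Blocked by slide their median was -0.90, and within slide 4 it was -0.76. Cybb itself fell by 0.80 (SE 0.175, adjusted p = 0.00542), by 0.55 with slide as a block (adjusted p = 0.158) and by 0.87 within slide 4. All 14 lists that camera called between the wild-type subsets were also called with slide as a block, while oxidative phosphorylation genes and Cybb lost their calls with the array signal described below as a covariate (adjusted p = 0.0769 and 0.08).

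In all, 3885 of 19464 genes were called between the wild-type subsets (20.0%), 2017 higher and 1868 lower in F4/80low, against 6538 at an unadjusted p under 0.05. With bounds counted, 2362 differed at least 2-fold, 1465 higher and 897 lower. The groups did not overlap for 7843 genes, where chance gives 10%. Slide as a block left 1665 called genes, 1510 of them shared and all 1510 in the same direction. Garnl3, Cd163, Ndufa1 and Hp were not called with the block. Without WT_low 2, 2528 genes were called. Scaling to the array median moved the median of all genes from 0.01 to -0.37 in this comparison and the share of calls that were higher from 51.9% to 22.8%, so directions are relative to the 75th percentile of each array.

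**Figure D2:**
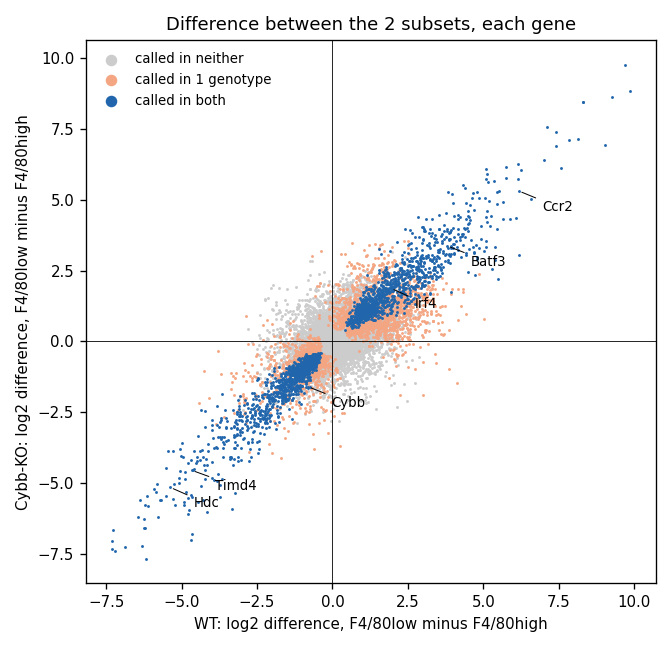
Log2 difference of each of 19464 genes between F4/80low and F4/80high cells, wild type on the horizontal and knockout on the vertical axis, with points for genes and labels for 6 of them. The values lie along a diagonal (r = 0.797 across genes), with Ccr2 at 6.17 and 5.31 and Timd4 at -4.66 and -4.55. All are fitted values, and that of Ccr2 in the wild type rests on WT_high signal not well above background. Among called genes, 654 in the wild type and 347 in the knockout have a group with no array well above background.

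The same comparison in the knockout asks whether the populations keep these differences without Cybb. The extremes were much alike: Ear2 (at least 247-fold), Ear12 (at least 199-fold), Upb1 (at least 97.2-fold), Cd226 (at least 77.4-fold), Gfra2 (at least 77.3-fold) and Itgax (at least 42.4-fold) were higher in F4/80low. Ear1 (8.85), Trerf1 (7.15), Gsn (7.11), Cx3cr1 (6.95) and Rnase2a (6.89) were higher too, each well above background on 1 of 3 KO_high arrays, as were Hr (6.39) and Ccr2 (5.31) on 2. The nuclear factor Tox2 (at least 100-fold), Serpinb2, the plasminogen activator inhibitor of macrophages (at least 60.3-fold), the prolyl hydroxylase Egln3 (at least 55.4-fold), the copper carrier Cp (at least 45.6-fold), Armc2 (at least 44.1-fold), Cald1 (at least 37.5-fold) and Cdkn2a (at least 28.8-fold) were lower. Fully measured genes that were lower included Ltbp1 (-6.58 ± 0.46, 95.7-fold lower), Fabp4 (-5.66 ± 0.32, 50.7-fold), the histidine decarboxylase Hdc (-5.15 ± 0.31, 35.6-fold) and Timd4 (-4.55 ± 0.28, 23.5-fold). Tgfb2 (-7.03), Garnl3 (-7.25) and Afap1l1 (-6.58) were well above background on 1 of 3 KO_low arrays and Fscn1 (-6.27) on 2.

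Large peritoneal macrophage genes fell in 20 of 22 cases and rose in 0 (median -3.86), including Vsig4 (-5.79, well above background on 2 of 3 KO_low arrays), Alox15 (-4.16 ± 0.25, 17.9-fold lower) and the lubricin gene Prg4 (-2.56). Small macrophage genes rose in 14 of 18 cases and fell in 0 (median 3.28), with Fcrls at 5.05 ± 0.25 (33.2-fold) and Mrc1 at 4.42 ± 0.33 (21.4-fold). MHC class II genes rose in 9 of 12 cases and fell in 0 (median 2.02), with H2-DMb2 at 5.41 ± 0.21 (42.6-fold) and H2-DMa at 2.10. Dendritic cell genes rose in 5 of 10 cases and fell in 0 (median 1.89, or 1.45 with bound genes at their bound), among them Cd209a (4.40 ± 0.31, 21.1-fold), Batf3 (3.37 ± 0.39, 10.3-fold) and the cytokine receptor Flt3 (at least 9.36-fold). Camera called these 4 with the estimated correlation too (adjusted p = 0.0179 each). The MHC class II list holds genes of the gate and was not tested without them, so its direction follows in part from the sort. Counts adjusted over the list alone were 1 higher and 20 lower, 16 and 0, 9 and 0, and 6 and 0. Blocked by slide the medians were -3.86, 2.79, 2.50 and 2.55, and within slide 2 they were -3.93, 2.91, 2.42 and 2.68. B cell genes rose in 4 of 11 cases (median 0.99, camera adjusted p = 0.00568), among them the adaptor Blnk (1.83), and the call was lost, at adjusted p = 0.0643 with an estimated correlation. Pax5 was not called here, at 0.48. T and NK cell genes rose in 2 of 9 cases, Cd2 (4.02) and Il2rb (1.58, well above background on 2 of 3 KO_high arrays), and the list was not called (median 0.85, camera adjusted p = 0.0996). Monocyte genes rose in 4 and fell in 1 of 10 cases, with Hp at -2.88 and Plac8 at 2.35, and the list was not called (median 0.53, adjusted p = 0.127). For these 3 lists, 5, 2 and 5 genes were higher and 0, 0 and 1 lower when adjusted over the list alone. Their medians were 1.48, 2.16 and 0.50 with slide as a block and 1.55, 1.91 and 0.59 within slide 2.

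Efferocytosis genes fell in 11 and rose in 2 of 21 cases (median -0.75), with Mfge8 at -3.05, Thbs1 at -3.48 and Cd93 at -2.72. Lysosome and autophagy genes fell in 11 of 21 cases (median -0.58), among them Lgmn (-1.71), Ctsd (-0.96) and Hexa (-0.96). NRF2 targets fell in 5 of 19 cases (median -0.38), with Txn1 at -1.61, Gsr at -2.36 and malic enzyme Me1 at least 11.4-fold lower. Antioxidant enzymes fell in 7 and rose in 1 of 15 cases (median -0.65), with Prdx6 at -1.61, Prdx4 at -1.65 and Gpx4 at -1.17. Oxidative phosphorylation genes fell in 11 of 31 cases (median -0.44), with Ndufa1 at -0.95 and Ndufa5 at -0.79. Alternative activation genes rose in 6 and fell in 2 of 12 cases (median 1.29), with Mgl2 at 2.16, Cd163 at 2.02 and Ccl24 at -1.61. Camera called these 6 lists (adjusted p = 1.13e-05, 8.87e-06, 0.00172, 0.000148, 3.33e-05 and 0.00807), and each call was lost, at adjusted p = 0.0897, 0.148, 0.197, 0.243, 0.346 and 0.148 with an estimated correlation. Adjusted over the list alone the higher and lower counts were 4 and 12, 0 and 13, 0 and 5, 1 and 11, 1 and 14, and 6 and 2. Slide-blocked medians were -0.71, -0.82, -0.71, -1.07, -0.68 and 0.94, and within slide 2 they were -0.94, -0.81, -0.68, -1.07, -0.58 and 0.96. Of the genes beside Cybb 1 of 6 fell, Mid1ip1 (-1.10), also when adjusted over the list alone, and the list was not called (median -0.52, or -0.20 with bound genes at their bound, camera adjusted p = 0.136). Cybb fell by 1.60 (SE 0.175, adjusted p = 2.14e-05), by 1.99 with slide as a block (adjusted p = 0.0086) and by 2.15 within slide 2. Blocked by slide, camera no longer called alternative activation and called other lists. KO_high 2 alone carries the KO_high level of that fit, so no list call is drawn from it. Oxidative phosphorylation and NRF2 targets lost their calls with the array signal described below as a covariate (0.087 and 0.0595).

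**Figure D3:**
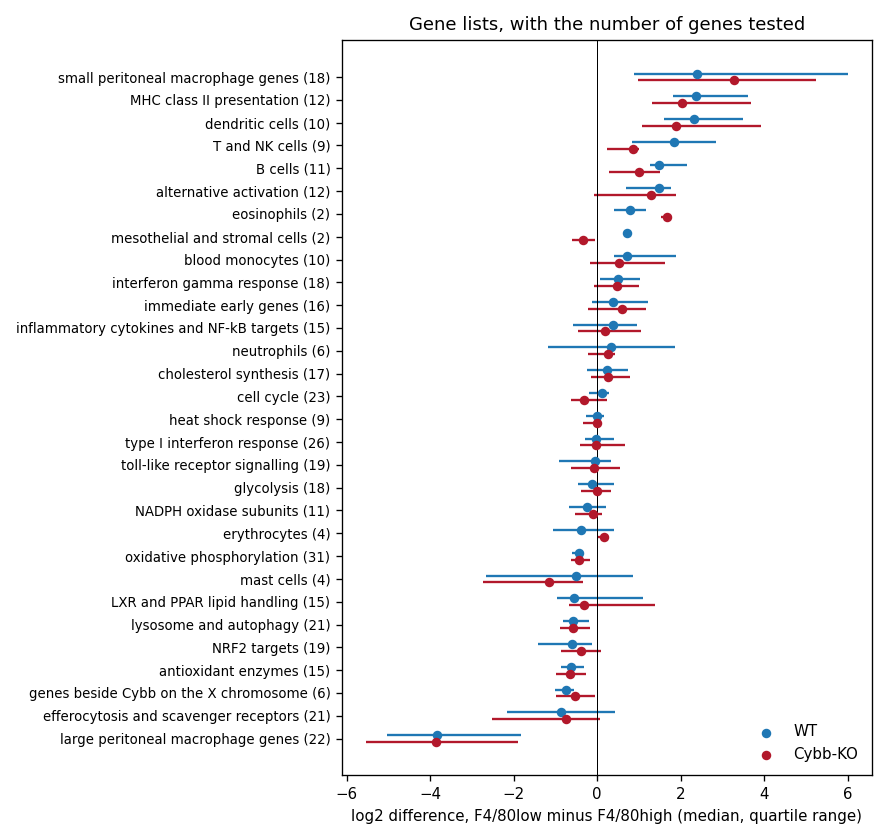
Median log2 difference between F4/80low and F4/80high cells of each gene list with its quartile range, for wild-type and knockout arrays. Large peritoneal macrophage genes lie lowest (-3.84 and -3.86), and small peritoneal macrophage genes lie highest (2.39 and 3.28).

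In the knockout 3043 genes were called (15.6%), 1447 higher and 1596 lower in F4/80low, against 5927 at an unadjusted p under 0.05. With bounds counted, 1935 differed at least 2-fold, 1077 higher and 858 lower. Both genotypes shared 1016 higher genes, where 149.9 would be shared by chance, and 1146 lower genes, where 153.2 would be, and 0 genes were called in opposite directions. Of the 1001 genes higher in the wild type alone, 964 had the same sign in the knockout, as did 688 of the 722 genes lower in the wild type alone. The interaction, which tests the difference between genotypes, called 0 genes, so a call in 1 genotype alone is not shown to differ from the other. With slide as a block KO_high 2 alone carries the KO_high level, so the calls of that fit are not counted here. Flt3 and Blnk were not called with the block. Without the block the count was 2029 when KO_low 3 was left out, and median scaling moved the share of calls that were higher from 47.6% to 23.0%. Of the named genes called between subsets, 93 in the wild type and 88 in the knockout kept their call whichever array was left out and 19 in each did not, among them Tspan7 in the wild type and Il2rb in the knockout.

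Knockout and wild type were compared next, first in F4/80high cells, to ask what loss of the oxidase subunit changes at rest. A single gene was called. Psg16, a member of the pregnancy-specific glycoprotein family, was higher in the knockout at 13.26 ± 0.36 against 11.76 ± 0.27 (log2 difference 1.5, SE 0.198, 2.83-fold, adjusted p = 0.038), with all 3 KO_high arrays above all 3 WT_high arrays. Its probe lies on mm9 chromosome 7 at 17718741 to 17718799 on the plus strand. Cybb stood at -1.09 (SE 0.175, 3 of 3 KO_high arrays below the others) and was not called, at adjusted p = 0.0851. Genes next in rank, none called, were Kctd17 (at least 4.66-fold higher, adjusted p = 0.0739), vasorin Vasn (at least 2.34-fold, 0.0851), Nrl (at least 2.36-fold, 0.201) and Syt2 (at least 1.42-fold, 0.217). Lower, and also not called, were the replication factor Gins1 (-1.70, 0.217), Zxdc (-1.71, 0.217), the lipase Ddhd2 (-3.30, well above background on 2 of 3 KO_high arrays, 0.25) and the NAD synthesis enzyme Nampt (-0.96, 0.269). Adjusted over the list alone, Cybb was lower among NADPH oxidase subunits, and 1 gene each was lower among small macrophage, MHC class II and LXR genes and 2 among dendritic cell genes. These were Cd209a (-1.44, in 2 of the lists), H2-DMb2 (-0.99), the acyltransferase Lpcat3 (-0.69) and Tbc1d4, well above background on 1 of 3 KO_high arrays. The chemokine Cxcl9 (at least 2.85-fold), the complement receptor Cr2 (1.48) and the neutrophil granule gene Camp, not well above background on any array of either group, were the 1 higher gene each of the interferon gamma, B cell and neutrophil lists adjusted over the list alone, and Car1 (at least 1.24-fold) that of the erythrocyte markers. Oxidative phosphorylation genes lay below 0 in 29 of 31 cases (median -0.22, camera adjusted p = 6.01e-06), led by Sdha (-1.40) and Sdhd (-1.06). NRF2 targets (median -0.24, adjusted p = 0.00111) and lysosome genes (median -0.16, adjusted p = 0.00741) were lower as lists too, with 0 genes of the 3 lists called. The calls were lost, at adjusted p = 0.444, 0.391 and 0.444 with an estimated correlation. Slide-blocked medians were 0.14, -0.13 and 0.08 and the calls ended. The KO_high level of that fit rests on KO_high 2 alone, the array with the lowest weight (0.373), so no list call, or loss of one, is drawn from it. In this subset no slide holds both groups, and without KO_high 1 or KO_high 3 the lysosome call was lost (adjusted p = 0.0934 and 0.0647). Neutrophil markers, 6 tested, had a median of 0.98, or 0.13 with bound genes at their bound, and only fry called them (FDR 0.0283).

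The calls of Psg16 and Cybb in F4/80high changed with the processing, while their differences lay between 1.24 and 1.93 and between -1.35 and -0.61 under all alternatives. Psg16 was not called with median scaling (adjusted p = 0.203), no mean-variance trend (0.0804), no filter (0.0662), the compared groups alone (0.477) or slide as a block (1.84, 0.495), and its adjusted p ranged from 0.00806 to 0.495 over all alternatives. It was also not called without WT_high 1 (0.13), WT_high 2 (0.0559), WT_low 1 (0.0899), WT_low 2 (0.0894), WT_low 3 (0.09), KO_high 1 (0.109), KO_high 3 (0.0545), KO_low 1 (0.0919) or KO_low 3 (0.0594). Cybb was called with quantile normalization (adjusted p = 0.00807), the deposited table (0.00806), array weights (0.0142) and without KO_high 2 (0.0333), and had its highest adjusted p with slide as a block (-0.61, 0.706). At an unadjusted p under 0.05 there were 2423 genes, 1807 higher and 616 lower, where chance gives 973.2. Groups were apart for 3119 genes. The count of calls was 0 without WT_high 1, any WT_low array, KO_high 1, KO_high 3, KO_low 1 or KO_low 3, 4 without KO_low 2, and 76 (69 higher) without KO_high 2. Kctd17 and Vasn were called without KO_high 2 (adjusted p = 0.0462 and 0.0444) and without KO_low 2 (0.0258 each), and Nrl and Syt2 without KO_high 2 (0.0332 and 0.0496).

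In F4/80low cells 3 genes were called. Cybb was lower in the knockout (-1.88, SE 0.175, 3.68-fold, adjusted p = 0.000522) and Psg16 higher, at 14.08 ± 0.03 against 12.63 ± 0.10 (1.45, SE 0.198, 2.73-fold, adjusted p = 0.0298). Adarb1, which encodes an RNA-editing adenosine deaminase, was at least 2.10-fold lower (adjusted p = 0.0377) and well above background on 3 WT_low and 0 KO_low arrays. All 3 genes had the groups' arrays apart. Genes next in rank, none called, were the chemokine receptor Cxcr3 (at least 3.81-fold lower, adjusted p = 0.157), hepatocyte growth factor Hgf (at least 1.82-fold, 0.188), the clock-output factor Tef (-1.05, 0.188), Ccdc183 (at least 3.01-fold higher, 0.188), Ehbp1 (at least 1.41-fold, 0.188), Mfsd2b (0.80, 0.212) and Catsperd (2.04, 0.212). Cystatin-like Stfa2 (at least 2.14-fold) and the G-CSF receptor Csf3r (0.46) were the 2 neutrophil genes higher when adjusted over the list alone, and Cybb was the 1 NADPH oxidase gene lower. Lists that camera called were all lower in the knockout. They were NADPH oxidase subunits (median -0.19, adjusted p = 0.0278), large macrophage genes (-0.17, 0.0212), type I interferon response (-0.21, 0.027), antioxidant enzymes (-0.23, 0.0299), oxidative phosphorylation (-0.18, 0.000508), cell cycle (-0.29, 0.0136), lysosome (-0.22, 0.0136), T and NK cells (-0.60, or -0.42 with bound genes at their bound, 0.0232) and blood monocytes (-0.30, 0.0321). The NADPH oxidase list includes Cybb, the disrupted gene, and was not tested without it. The calls were lost, at adjusted p = 0.36 for NADPH oxidase, interferon, cell cycle, lysosome, T and NK cell and monocyte genes and adjusted p = 0.428 for the other 3 with an estimated correlation. Vsig4 (-1.09, well above background on 2 of 3 KO_low arrays), the peroxiredoxin Prdx4 (-0.93), the nucleotide kinase Cmpk2 (-1.36), the helicase components Mcm4 (-0.97) and Mcm6 (-0.94) and Thy1 (-1.48) were among their members, none called. Slide-blocked medians of the 9 lists, in the order given, were -0.10, -0.55, -0.18, -0.28, -0.04, -0.55, -0.18, -0.23 and -0.54, and within slide 2 they were 0.03, -0.86, -0.25, -0.17, 0.01, -0.25, -0.36, -0.69 and -0.68. The block ended the calls of NADPH oxidase (adjusted p = 0.107), interferon (0.0903), oxidative phosphorylation (0.266) and T and NK cell genes (0.171). It added lower inflammatory (0.0283), efferocytosis (0.0459), LXR (0.0193) and cholesterol synthesis genes (0.0316) and higher MHC class II genes (0.0459).

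At an unadjusted p under 0.05 there were 2368 genes in F4/80low, 1676 higher and 692 lower, and groups were apart for 3662. With slide as a block 0 were called, and Cybb stood at -2.05 (adjusted p = 0.238), Psg16 at 1.65 (0.238), against -2.37 and 1.47 within slide 2, while Adarb1 had an adjusted p of 0.46. Over all alternatives the adjusted p of Cybb ranged from 3.18e-05 to 0.238, that of Psg16 from 0.00688 to 0.238 and that of Adarb1 from 0.0181 to 0.615. Psg16 was not called with median scaling (0.227) or no mean-variance trend (0.0946), nor Adarb1 with normexp background correction (0.271, where its fitted value, which rests on KO_low signal not well above background, went from -2.97 to -0.89), the compared groups alone (0.183), every probe tested (0.0513), the arrays of slide 3 left out (0.18), replicates as a block (0.136) or the mean signal of olfactory, vomeronasal and taste receptor genes as a covariate (0.615). Cybb kept its call without each array (adjusted p = 0.000436 to 0.00826). Psg16 lost it without WT_high 1 (0.0574), WT_low 1 (0.141), WT_low 2 (0.0993), WT_low 3 (0.101), KO_high 1 (0.0539), KO_low 1 (0.138), KO_low 2 (0.121) or KO_low 3 (0.151), and Adarb1 without every array but WT_low 1 (0.0712 to 0.171). The count fell to 1 without WT_high 1, KO_high 1, KO_low 1, KO_low 2 or KO_low 3. Of the 9 lists only oxidative phosphorylation kept its call without each array. Without WT_low 3 the adjusted p of 7 lists rose to between 0.11 and 0.92, the last for large macrophage genes, whose direction turned. Without KO_low 3 it was 0.0546 to 0.189 for antioxidant, interferon, cell cycle and monocyte genes, and without KO_low 1 it was 0.0533 to 0.0865 for NADPH oxidase, antioxidant, T and NK cell and monocyte genes. NADPH oxidase genes were also lost without WT_low 1 (0.0991) and KO_low 2 (0.0749), antioxidant enzymes without WT_low 1 (0.181) and interferon genes without WT_low 2 (0.126).

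Averaged over both subsets, Cybb was lower (-1.48, SE 0.124, 2.80-fold, adjusted p = 0.000125) and Psg16 higher in the knockout (1.47, SE 0.140, 2.78-fold, adjusted p = 0.000326), in both subsets and without any overlap of arrays. These were the 2 called genes, and both calls were kept without each array (adjusted p up to 0.00244 for Psg16). With slide as a block neither was called, at -1.33 (SE 0.181) for Cybb and 1.75 (SE 0.166) for Psg16. That fit has 3 residual degrees of freedom and rests on KO_high 2 alone among the KO_high arrays. The end of these calls there does not show smaller differences. Psg16 lost its call with median scaling (adjusted p = 0.0605) and Cybb with the same covariate (-1.29, 0.184). Next in rank, at adjusted p = 0.0682, came the mannose-binding lectin Mbl1 (1.19), Ccdc85b (0.99), Cr2 (1.17), Nampt (-0.93) and, well above background on no KO_low array, Hgf and Adarb1. Ccdc183 and Mrgprf, well above background on 3 of 12 arrays each, Stfa2, and Cxcr3, well above background on the 3 WT_low arrays alone, stood at the same adjusted p. Lists called by camera were again all lower: oxidative phosphorylation (median -0.23, adjusted p = 6.91e-07), lysosome (-0.21, 0.00174), type I interferon response (-0.21, 0.0213), NRF2 targets (-0.17, 0.0213), NADPH oxidase, which includes Cybb itself (-0.14, 0.0258), cell cycle (-0.25, 0.0258) and antioxidant enzymes (-0.14, 0.0331). Sdha (-0.78), Prdx1 (-0.36), Prdx4 (-0.79) and the lysosomal cholesterol carrier Npc1 (-0.44) were among their members, none called. The calls were lost, at adjusted p = 0.371, 0.351, 0.351, 0.351, 0.351, 0.444 and 0.518 with an estimated correlation, and slide-blocked medians were 0.07, -0.07, -0.19, -0.14, -0.12, -0.10 and -0.04. With slide as a block these 7 lists were not called and other lists were. Blocked medians of the latter were 0.30 for small macrophage, 0.38 for MHC class II and -0.89 for T and NK cell genes. They were -0.39 for large macrophage, -0.27 for LXR, -0.17 for efferocytosis and -0.35 for monocyte genes. In that fit KO_high 2 alone carries the KO_high level, so nothing is drawn from the loss of calls there or from its list calls. These and the other slide-blocked list calls rest on camera's preset correlation, were not tested with an estimated one, and in simulated data that test gave an unshifted list p = 0.0346 in the average. NRF2 targets lost their call without KO_high 3 (adjusted p = 0.0632), cell cycle genes without WT_high 2 (0.0781), KO_high 3 (0.0833) or KO_low 3 (0.132), and antioxidant enzymes without WT_high 1 (0.067), WT_low 1 (0.0823), WT_low 3 (0.0801) or KO_high 3 (0.197). Neutrophil markers (median 0.63) were called by fry (FDR 0.0266) and not by camera (adjusted p = 0.0512). Adjusted over the list alone, Cybb, Lpcat3 (-0.56) and H2-DMb2 (-0.47) were lower in the NADPH oxidase, LXR and MHC class II lists. The class II transactivator Ciita (0.37), Cr2 (1.17), Krt18 (0.61), Car1, well above background on 5 of 12 arrays, Csf3r (0.36) and Stfa2 were higher in the MHC class II, B cell, stromal, erythrocyte and neutrophil lists.

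**Figure D4:**
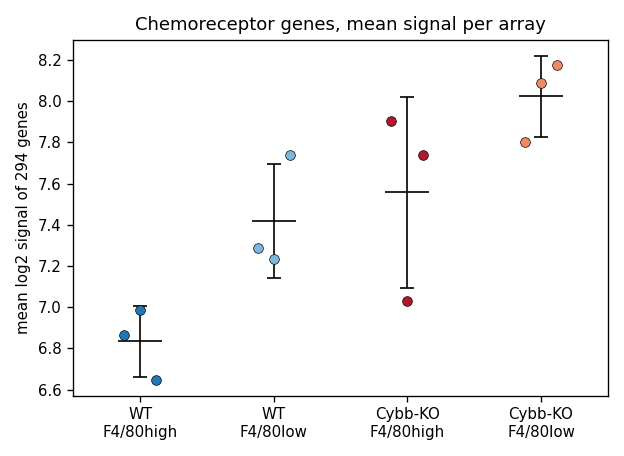
Mean log2 scaled intensity of 294 olfactory, vomeronasal and taste receptor genes on each array of the 4 groups, with dots for arrays, a bar at the mean of 3 arrays and a line of 1 SD. Knockout arrays lie at 7.03 to 8.17 and wild-type arrays at 6.65 to 7.74.

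Weak signals moved with genotype beside these gene groups. Olfactory, vomeronasal and taste receptor genes, which have their known function in sensory cells and were singled out after the data were seen, had a mean signal 0.66 higher in the knockout (SE 0.173), 0.72 in F4/80high and 0.60 in F4/80low. In F4/80high the excess lay in the slide 3 arrays KO_high 1 (7.90) and KO_high 3 (7.74), while KO_high 2 (7.03, with the lowest array weight, 0.373) lay beside the WT_high arrays (6.65 to 6.99). With slide as a block the difference was 0.09 (95% interval -0.20 to 0.38), with -0.18 (-0.66 to 0.30) in F4/80high and 0.37 (0.01 to 0.72) in F4/80low. The average and the F4/80high value rest on KO_high 2 alone among the KO_high arrays. The F4/80low value takes nothing from WT_low 2 or KO_low 2, which lay alone on their slides. The same signal was also higher in F4/80low than in F4/80high cells, by 0.59 (95% interval 0.02 to 1.15) in the wild type and 0.47 (-0.10 to 1.03) in the knockout, and by 0.57 (0.21 to 0.92) and 1.11 (0.69 to 1.53) with slide as a block. With it as a covariate, an alternative chosen after the data were seen, the lists called between subsets kept their calls apart from oxidative phosphorylation in both genotypes and NRF2 targets in the knockout, and interferon gamma (adjusted p = 0.019) and immediate early genes (0.0213) gained one in the wild type. The lowest intensity decile of genes had a median genotype difference of 0.42, with 368 genes higher and 28 lower at an unadjusted p under 0.05, while the seventh, the eighth and the ninth decile had medians of -0.07, -0.10 and -0.10. More genes were higher than lower at that p in every decile, at 290 and 150, 241 and 201, and 215 and 186 in these and at 270 and 61 in the brightest, whose median was -0.02. Over all genes 3938 had an unadjusted p under 0.05, 2950 higher and 988 lower, against 1233 with slide as a block, 1238 with the covariate and 1973 without the arrays of slide 3, where chance gives 973.2. At an adjusted p under 0.1 there were 986, 886 of them higher. The count of called genes was 4 without WT_high 2, 331 (317 higher) without WT_low 3 and 1672 (1509 higher) without KO_high 2. Ccdc183, Mbl1, Ccdc85b, Mrgprf, Nampt, Cxcr3, Hgf and Adarb1 were called without KO_high 2 (adjusted p = 0.0115 to 0.0187) and without WT_low 3 (0.0412 to 0.0449). Across genes, which are not independent replicates, the genotype differences of the subsets correlated at r = 0.407 (Spearman's rho 0.439), and 67.4% of genes had the same sign. With slide as a block r was -0.0916, and without the arrays of slide 3 it was 0.0795. Each of these leaves KO_high 2 as the only KO_high array behind r, so they are not separate checks.

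The interaction asks whether loss of Cybb acted differently in the subsets. In limma 0 genes were called, and the smallest adjusted p was 0.202. At an unadjusted p under 0.05 there were 696 genes, 317 higher and 379 lower, fewer than the 973.2 that chance gives. The smallest p values belonged to the Notch-pathway ubiquitin ligase Dtx1 and to Kctd17, both lower at adjusted p = 0.202 and well above background on no WT_high array, and Kctd17 alone was called without KO_low 2 (0.0395). Others in rank, all at adjusted p = 1, were Mboat7 (1.26), Mettl22 (2.44), Zxdc (1.93) and, each with a group that was well above background on no array, Ehbp1, Vasn, Adarb1 and Ptprq. Cybb stood at -0.80 (SE 0.248), also at adjusted p = 1. T and NK cell markers had a median of -1.06 (camera adjusted p = 0.0134), with Cd3d at -1.85, and blood monocyte markers of -0.71 (adjusted p = 0.032), with Plac8 at -2.38, and 0 genes of either list were called. In a single draw of simulated data the same test gave an unadjusted p of 0.00338 to a list without any shift. The calls were lost, at adjusted p = 0.703 and 0.327 with an estimated correlation. Slide-blocked medians were 0.64 and -0.66, in a fit whose KO_high level rests on KO_high 2 alone. T and NK markers lost their call without WT_high 2 (adjusted p = 0.123), WT_low 3 (0.0869), KO_high 1 (0.0992) or KO_high 3 (0.109), and monocyte markers without WT_high 2 (0.113), WT_low 3 (0.126), KO_high 1 (0.0768), KO_high 3 (0.109), KO_low 1 (0.0633) or KO_low 3 (0.184). Adjusted over the list alone, Ccl5 (-1.34) and Pax5 (-1.57) were lower among inflammatory and B cell genes, and H2-DMb2 (1.03) and Cd209a (1.56) higher among MHC class II and dendritic cell genes.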

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

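The splits of the arrays were chosen before their results were seen. The slope test of weak signals was chosen after the chemoreceptor signal had been seen in the data and before its own result, and the other tests of this part, with slide as a block, a covariate, other probes, neighbouring genes or a permutation, were chosen after.

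The genotype effect on T and NK cell markers differed between the subsets by camera's test of the interaction (adjusted p = 0.0134, median -1.06, 7 of 9 genes below 0). The same test gave adjusted p = 0.032 for blood monocyte markers (median -0.71, 8 of 10 genes below 0). With an estimated correlation the adjusted p was 0.703 and 0.327. Of 100 splits of the arrays 82 called at least the 2 lists of the real split, and the highest other split called 11, so chance is not excluded for either.

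Genes with weak signal were higher in the knockout. An excess of higher genes was not confined to them. The brightest decile had 270 genes higher and 61 lower at an unadjusted p under 0.05, although its median was -0.02, and the strict filter, which removes dim probes, gave 220 of 231 calls higher. Without slide 3 the calls of the average were 2 higher and 9 lower, and the excess among bright genes was not tested separately. Across 19091 genes the slope of a gene on the arrays' mean chemoreceptor signal within groups correlated with its genotype difference at r = 0.467, above the 95th percentile of 100 permuted covariates (0.344) and below the highest of them (0.472), which is consistent with a non-specific signal that varies from array to array. The genotype difference of that signal, 0.66, became 0.0929 with slide as a block (95% interval -0.20 to 0.38), an interval that excludes the unblocked value. In that fit KO_high 2 alone carries the KO_high level, and its own signal (7.03) lies beside the WT_high arrays (6.65 to 6.99). The fall therefore cannot tell an effect of slide from a difference of that array. An effect of genotype stays open, since the exact permutation within subsets gave p = 0.005, the smallest that 400 labellings can give, and no slide holds WT_high with KO_high. In F4/80low, where slide 2 holds both genotypes, the blocked difference was 0.37 (95% interval 0.01 to 0.72). That value takes nothing from WT_low 2 or KO_low 2, which lay alone on their slides. In F4/80high, where no slide does, 0.72 became -0.18 (-0.66 to 0.30), a value that rests on KO_high 2 alone among the KO_high arrays.

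Psg16 was higher in the knockout in both subsets. With the chemoreceptor signal as a covariate its average difference was 1.86 (SE 0.186, adjusted p = 0.00447, with 6.22e-05 to 0.188 over all alternatives), which argues against that signal as its cause. Whether the probe reads the transcript of another gene cannot be told apart, as the other Psg16 probes were well above background on at most 1 array. Psg16 lies on another chromosome than Cybb, so a segment linked to the altered Cybb allele does not reach it. A segment around Psg16 from the strain background might still change several neighbours. Of 34 tested genes within 1 Mb 4 had an unadjusted p under 0.05 (11.8%, 95% interval 3.30% to 27.5%, against 20.2% of all genes, one-sided Fisher's exact p = 0.934). That interval also includes the share of all genes. A direct effect of Cybb loss on Psg16 stays open and was not tested.

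Oxidative phosphorylation and lysosome genes were called lower in the knockout as lists by camera with its preset correlation, with 0 members called. Both calls ended in the average in camera with an estimated correlation (adjusted p = 0.371 and 0.351), so that a lower level is not established. With slide as a block the medians were 0.07 and -0.07, in a fit whose KO_high level rests on KO_high 2 alone. The mean of their 52 genes differed by -0.21 (SE 0.0767) and by 0.041 (SE 0.0725) with the chemoreceptor signal as a covariate, and it changed with that signal within groups at a slope of -0.376 (SE 0.088). This is consistent with the same array-to-array signal as a candidate explanation. An effect of genotype stays open, as knockout and wild type also differ in that signal, and slide is partly confounded with genotype.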

How the results depend on the processing

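The alternatives with a chemoreceptor covariate, without the arrays of slide 3 and with cyclic loess normalization were chosen after seeing the data, the others before; unless a sentence gives one, the cause was not tested. In F4/80high, where 1 gene was called, the genotype comparison gave 2 with quantile normalization, 0 with median scaling, 2 with the deposited table, 0 without a filter, 2 without a mean-variance trend, 7 with array weights, 0 in the 2 groups only, 0 with the replicate block (a paired fit), 0 with slide as a fixed block, 43 without slide 3 (7 higher, 36 lower; 1 KO_high array is left and assumed to vary like the other groups) and 0 to 76 without each array. The replicate block ended the calls of Psg16 in F4/80high (adjusted p = 0.0913) and F4/80low (0.102) and of Adarb1 (0.136), which also lost its call without slide 3 (0.18). In F4/80low, where 3 were called, it gave 10 without a filter, 1 with the replicate block, 0 with slide as a fixed block and 1 to 3 without each array. The average, with 2 called genes, gave 1 with median scaling, 231 (220 higher) with the strict filter, where fewer genes are tested, 6 without a trend, 1826 (1624 higher) with array weights, 0 with slide as a fixed block, 1 with the covariate, where Cybb stood at -1.29 (adjusted p = 0.184), 11 (2 higher, 9 lower) without slide 3 and 2 to 1672 without each array. The interaction called 0 genes and 0 to 1 without each array. Between wild-type subsets 3885 genes became 1665 with slide as a fixed block, 2322 with the covariate and 2528 to 4559 without each array. Between knockout subsets 3043 became 1921 in the 2 groups only, while the wild-type count rose to 4501, and 2029 to 2904 without each array. Median scaling called 5118 genes in the wild type (1165 higher, 3953 lower) and 3393 in the knockout (781 and 2612), and the strict filter made 41.5% of wild-type calls higher. With median scaling the median of all genes went from 0.04 to -0.23 in F4/80high, from 0.05 to -0.13 in F4/80low, from 0.03 to -0.19 in the average and from 0.06 to -0.24 between knockout subsets. Of 46 list calls 9 were left with an estimated correlation, and 37 to 54 were found without each array. Among the 9 is MHC class II presentation in both genotypes, a list that holds genes of the gate. The correlation of genotype effects, 0.407, turned to -0.0916 with slide as a fixed block, was 0.0795 without slide 3 and lay between 0.312 and 0.454 without each array. With the block and without slide 3 this correlation rests on KO_high 2 alone among the KO_high arrays. Directions turned for Gpi1 between wild-type subsets with normexp (0.0023) and for lists, given by adjusted p. With slide as a fixed block these were oxidative phosphorylation in F4/80high (0.0916) and in the average (0.397), lysosome in F4/80high (0.667) and T and NK cells in the interaction (0.454). With the covariate they were oxidative phosphorylation in F4/80high (0.436), F4/80low (0.371) and the average (0.2997), lysosome in F4/80high (0.894) and NRF2 targets in the average (0.957). Without slide 3 they were oxidative phosphorylation (0.933) and lysosome (0.853) in F4/80high, and without WT_low 3 large macrophage genes in F4/80low (0.92, the highest of 2.6e-05 to 0.92 without each array). Over all alternatives, named genes kept direction and side of the threshold in 6920 cases, lost a call in 447, gained one in 46 and turned in 1; for lists the counts were 4161, 172, 132 and 12, with 41 further values moved. Lists had no value with every probe tested, in the 2 groups only or with slide as a random block, whose consensus correlation was -0.0178. Replicate numbers did not pair the arrays, as deviations of arrays with the same number correlated at -0.193 to 0.145, and 2 of 18 such pairs passed 0.1. Signal over background limits the rest: 654 wild-type and 347 knockout calls between subsets rest on a group with no array well above background and give bounds only, and how far a difference in such genes exceeds its bound could not be measured.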

Other observations

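The splits of the arrays reported in this part were chosen as tests before their results were seen.

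Signalling and metabolic lists that camera did not call between the subsets still held large differences in single genes. Of 19 toll-like receptor genes 2 rose and 5 fell in wild-type F4/80low cells (camera adjusted p = 0.347) and 2 rose and 4 fell in the knockout (0.676). Tlr13, which senses bacterial ribosomal RNA, was 6.95-fold lower in the wild type (-2.80 ± 0.31, SE) and 8.28-fold lower in the knockout (-3.05 ± 0.31), while Tlr9 was higher in the wild type (1.35) and Irf5 in the knockout (1.11). Immediate early genes rose in 5 and fell in 1 of 16 cases in the wild type (adjusted p = 0.201) and rose in 4 and fell in 2 in the knockout (0.226), with Egr2 at 2.99 (KO) and Fos at least 2.60-fold higher (WT) against Klf2 at -0.96 and -1.13. Inflammatory genes rose in 2 and fell in 2 of 15 cases in each genotype (adjusted p = 0.754 and 0.896), with interleukin Il1b at 1.99 (WT, well above background on 2 of 3 WT_high arrays) and 1.84 and the signalling inhibitor Socs3 at -1.45 and -1.56. Interferon gamma genes rose in 4 and fell in 1 of 18 cases in the wild type (0.0835) and rose in 2 and fell in 1 in the knockout (0.183), and in the wild type this list and immediate early genes were called with the chemoreceptor signal as a covariate, an alternative chosen after the data were seen (0.019 and 0.0213). The chemokine Cxcl9 was at least 5.78-fold higher in the wild type and not called in the knockout (0.99), and the transcription factor Irf8 was lower in both (-1.48 and -1.54). Type I interferon genes rose in 3 and fell in 1 of 26 cases in the wild type (0.932; median -0.02 but mean 0.22) and rose in 2 and fell in 3 in the knockout (0.916; median -0.04, mean 0.13), with the antiviral GTPase Mx1 at least 4.49-fold and at least 3.94-fold higher. Fos, Egr2, Mx1 and, in the knockout, Il1b and Irf8 were not called with slide as a block. These 5 lists had higher and lower counts adjusted over the list alone of 2 and 5, 6 and 1, 3 and 3, 4 and 1, and 2 and 1 in the wild type and 3 and 4, 6 and 3, 3 and 3, 2 and 1, and 2 and 4 in the knockout.

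Lipid and energy genes went both ways. Cholesterol synthesis genes rose in 3 and fell in 1 of 17 cases in the wild type (camera adjusted p = 0.354) and rose in 2 and fell in 1 in the knockout (0.26). LXR and PPAR genes rose in 3 and fell in 6 of 15 cases and rose in 2 and fell in 6 (0.117 and 0.103), Fabp4 being the lowest, while the desaturase Scd2 was at least 4.02-fold and at least 4.0-fold higher. Glycolysis genes rose in 2 and fell in 4 of 18 cases in each genotype (0.43 and 0.469), with the kinase Pdk1 at -2.09 in the knockout. NADPH oxidase genes rose in 1 case, Ncf4, and fell in 2, Cybb and the proton channel Hvcn1, of 11 in each genotype (0.234 and 0.168), and Ncf4 in both genotypes and Hvcn1 in the wild type did not keep their call without each array. For these 4 lists the higher and lower counts adjusted over the list alone were 3 and 1, 3 and 7, 3 and 5, and 1 and 4 in the wild type and 3 and 1, 4 and 6, 2 and 5, and 1 and 4 in the knockout. Of 23 cell cycle genes and of 9 heat shock genes 0 were called in either genotype by limma (camera adjusted p = 0.932 and 0.26, and 0.896 and 0.676), and the cell cycle list had a median of 0.11 with a test towards lower values in the wild type. Among neutrophil markers 2 of 6 rose and 1 fell in the wild type (0.567) and 1 rose and 1 fell in the knockout (0.709), with the calprotectin chain S100a8 at least 2.95-fold and at least 1.96-fold lower. Of the 4 mast cell genes tested, Hdc was lower (-5.38 ± 0.31, 41.5-fold, and -5.15 ± 0.31, 35.6-fold), and Tpsb2, Mcpt4 and Cma1, which mast cells express most strongly, were not called. Eosinophil, stromal and erythrocyte markers had 2, 2 and 4 tested genes with 0 called.

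The median and the mean or the camera direction of a list differed in sign in some uncalled lists. Between knockout and wild type in F4/80high these were small macrophage (median -0.09, mean 0.01), interferon gamma (-0.08, 0.11), glycolysis (0.01, -0.02), alternative activation (-0.02, 0.10), immediate early (-0.12, 0.01) and dendritic cell genes (0.15, -0.06). In F4/80low they were glycolysis, cholesterol synthesis, alternative activation, dendritic and mast cell genes, and in the average small macrophage, interferon gamma, alternative activation, B cell and dendritic cell genes and those beside Cybb. In the interaction they were MHC class II, type I interferon, glycolysis, alternative activation, toll-like receptor and dendritic cell genes, and between subsets heat shock genes in addition to the lists named above.

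Splits of the arrays into groups of the same size were counted for each comparison. The 10 splits of 3 arrays against 3 are too few for a share under 0.05. For genotype in F4/80high, 3 splits called at least the 1 gene of the real split and another called 85, and 6 called at least the 3 real lists, the highest other calling 8. The split with 85 genes sets WT_high 2 and both arrays of slide 3 against the rest, which points to a structure of the samples other than genotype. WT_high 2 is also the only array with an age of 12 weeks, and age was not tested. No slide holds both groups, and the slide-blocked count was 0. In F4/80low the real split alone reached its 3 genes (1 split, highest other 1) and its 9 lists (1 split, highest other 8). Cybb, the disrupted gene, is 1 of these 3 genes. Between subsets the real split alone reached 3885 genes in the wild type (1 split, highest other 1) with 14 lists (1 split, highest other 12), and 3043 genes in the knockout (1 split, highest other 1) with 11 lists (1 split, highest other 10). For the average, 3 of 100 splits called at least the 2 real genes, the highest other calling 13, a share under the 0.05 set beforehand. Cybb, the disrupted gene, is 1 of the 2, so the count says little about genes beyond it. The splits do not take slide into account, and slide is partly confounded with genotype. This share therefore does not exclude a grouping of arrays by slide as the source of the count. At least the 7 real lists were called by 15 of 100 splits, the highest other calling 11, so chance is not excluded for the lists. All 100 splits reached the 0 genes of the interaction, and the highest other called 2. The correlation of genotype effects was reached by 1 of 100 splits, the real one (0.407 against 0.3985), also a share under 0.05. The margin over the next split is small and the splits ignore slide, so a grouping of arrays by slide is not excluded. Slide as a block turned the sign of the correlation, in a fit whose KO_high level rests on KO_high 2 alone.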
